A study of Homo sapiens with 6 samples.

How the data were processed

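Total RNA of 6 SCC4 libraries was sequenced as single-end short reads on a BGISEQ instrument, per the labels' protocols. The submitters' processing notes name HISAT and Bowtie2, without versions, and the mouse build GRCm38.p6, although the organism label, the cell line and all 16536 gene identifiers are human. The build and annotation used for these human reads, the quantifier and the gene filter are not given in the sources used here, so no coordinates are printed. Gene symbols are those paired with the identifiers in the deposited table, and 16451 of the 16536 identifiers were found in a current gene name table, which was used only to match list genes under older symbols.

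The deposited values are named as TPM but are treated here as a signal, a normalised expression value on a TPM-like scale, because their column totals differed from 1 library to another. In each library the low values lay on steps of 1 constant, between 0.8864 and 1.136. Dividing by it brought every total to between 998329 and 999167 and left 92.4% to 100% of values below 100 units within 0.1 of a whole number. This division is called undoing the authors' scaling below, and it would not undo an adjustment of single genes. For genes with means of 20 to 50 of these whole numbers, the median ratio of variance to mean among replicates was 0.27 in parental and 0.19 in sphere cells, below the median of 0.69 that 3 replicates would give if each whole number were a count of reads with counting error alone. For means of 50 to 100 it was 0.66 in parental cells, close to that value, and 0.38 in sphere cells. The whole numbers were therefore not used as reads, and no count model was run. The test design had been fixed for TPM, and the same log-scale test was kept for these values. A value near 1 unit is 1 rounding step. Zeros are described as listed at 0, and no fold is given against a group listed at 0.

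Values were analysed as log2(value + 1), so fold changes of low genes are understated. Genes of at least 1 unit in at least 3 of the 6 libraries were fitted with limma 3.58.1 in R 4.3.3, with a 2-group model and moderated variances with a mean trend, two-sided, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p of 0.05, and a second count required a log2 fold change of at least 1 in size. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 43 lists with at least 5 tested members. Errors after ± are SDs over 3 libraries. On simulated data for this comparison with 15034 genes, the procedure recovered 46% of genes changed by a log2 value of 0.5. It recovered 94% at 1, 98% at 2 and 96% at 3, and called 11 unchanged genes. The simulation changed only a small share of the genes, all above about 5 units, with independent normal noise and no rounding steps. These rates therefore do not describe low genes, or a comparison with as many calls as this one.

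The text names the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 units in the higher group and no overlap between groups, leaving out identifier-only names. From each list described it names up to 4 members with the smallest p, and any member of the 2 stem cell lists with a mean of at least 1 unit in either group. Of the genes this rule picks, 1 is not reported here. The groups, tests, lists, naming rule and most other settings were set before the data were examined. Those settings were other pseudocounts, filters, scalings and variance models, a replicate block and each library left out. Leaving out the 3 libraries with erythroid transcripts, an estimated correlation without these libraries or without parental replicate 3, averaging sphere replicates 1 and 3, undoing the authors' scaling and leaving out mitochondrially encoded genes were added after the data were seen.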

Results

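RNA was sequenced from SCC4, an established human cell line derived from a squamous carcinoma of the tongue. There were 2 groups of 3 libraries, parental cells grown attached to the dish and sphere cells obtained from them by growth in suspension, which the submitters describe as isolated cancer stem cells. The comparison asks how the transcriptomes of the 2 culture forms differ. The deposited table held 16536 genes in normalised expression units on a TPM-like scale, and 15034 genes reached 1 unit in at least 3 of the 6 libraries and were tested. The column totals were 885258, 1007523 and 944432 units in parental replicates 1 to 3 and 1032639, 1134102 and 1007357 units in sphere replicates 1 to 3. These totals are set by the authors' scaling, so the read depth behind each value is unknown and no counting interval is given. The labels do not say whether replicates were separate cultures, and p-values then measure only the spread between these libraries, which may be technical. The deposited values may also have been adjusted jointly within each group. Each of the 3 sphere libraries lists 434 genes at 0. DHRS2, at 2.179 units in sphere replicate 2, has 0.00566 and 0.00144 units in sphere replicates 1 and 3 rather than 0. Such an adjustment could make the spread between replicates, and so the p-values, too small. Its effect on them was not tested.

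Libraries lay closest to those of their own group. Pearson's r over tested genes was 0.973 to 0.977 among parental libraries, 0.982 to 0.993 among sphere libraries and 0.931 to 0.95 between the groups. The first principal component held 64.6% of the variance and separated the groups. Sphere replicates 1 and 3 had the highest correlation, yet their median absolute log2 difference over genes of at least 50 units, 0.057, was close to the 0.06 and 0.059 of the other sphere pairs. After division by each library's step constant and rounding, 20.2% of genes with a mean of at least 5 held equal whole numbers in this pair, against 13.7% and 8.9% in the other sphere pairs. As most values differed, they were kept as separate replicates. Averaging them as 1 replicate, a choice made after the data were seen, called 6302 genes, 1529 at least 2-fold and 15 lists. A second feature cut across the groups. Transcripts typical of red-cell precursors were present in parental replicates 2 and 3 and sphere replicate 2. There the globin genes summed to 1905.4, 1239.5 and 914.4 units, against 0, 0.9 and 0.2 units in parental replicate 1 and sphere replicates 1 and 3. The feature was not limited to erythroid genes. By a rule set after the data were seen, 31 genes of the table had at least 5 units in each of these 3 libraries and at least 2 times the highest value of the other libraries of the same group, and 26 of them were not on the list of erythroid markers. The other 8 choices of 2 parental libraries and 1 sphere library gave at most 1 such gene. Among the 26 were APOC1, PRG2, PRAME, NMU and VIM, the oxidative phosphorylation genes COX5B and COX6A1, and the ribosomal protein genes RPS10, RPS18 and RPS21. RPS18 was at 6750.3 and 4565.9 units in parental replicates 2 and 3 and 28800.6 units in sphere replicate 2, against 1870.1, 2340.2 and 2330.4 units in the other libraries.

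**Figure D1:**
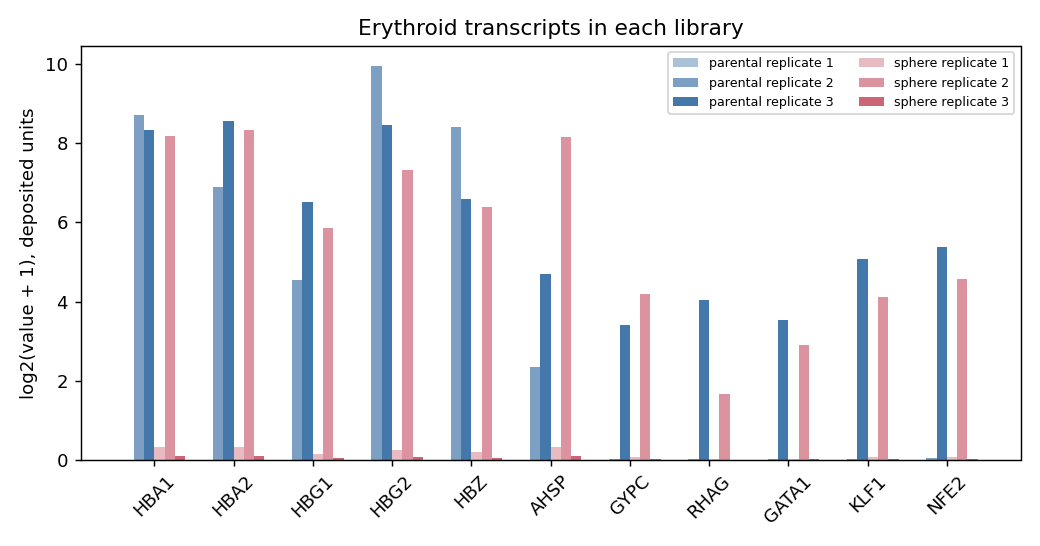
Values of 11 erythroid genes, chosen after their values were seen, in each of the 6 libraries on the log2(value + 1) scale of the deposited units, with bars coloured by group and shaded by replicate. Globin bars stand high in parental replicates 2 and 3 and sphere replicate 2. GYPC, RHAG, GATA1, KLF1 and NFE2 stay near 0 in parental replicate 2, where AHSP is at 4.05 units. RHAG is at only 2.18 units in sphere replicate 2.

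On the log2(value + 1) scale, the largest rises in sphere cells included the keratin gene KRT1, the metalloproteinase genes MMP1 and MMP10 and the chemokine gene CCL2, and the largest falls included GDF15, UPP1, TRIB3 and the keratin gene KRT80. KRT1 (ENSG00000167768), a keratin of suprabasal epidermal layers, had the largest rise on this scale, from 2.22 ± 1.51 units in parental cells to 212 ± 32.5 units in sphere cells (SD, n = 3 each). MMP1 (ENSG00000196611), an interstitial collagenase, rose from 5.66 ± 0.835 to 378 ± 6.98 units, and MMP10 (ENSG00000166670), a stromelysin, from 2.51 ± 0.431 to 185 ± 8.9 units. OLFM4 (ENSG00000102837), CCL2 (ENSG00000108691), KRTDAP (ENSG00000188508), LOXL4 (ENSG00000138131) and C10orf99 (ENSG00000188373) completed the 8 largest rises, with log2 fold changes of 5.54, 5.35, 5.30, 4.89 and 4.84. The largest fall on this scale was in GDF15 (ENSG00000130513), a stress-induced cytokine, from 249 ± 17.1 to 18.9 ± 8.81 units. UPP1 (ENSG00000183696), uridine phosphorylase, fell from 566 ± 32.7 to 62.6 ± 1.67 units, and TRIB3 (ENSG00000101255), a pseudokinase induced by ATF4, from 451 ± 32.8 to 51.3 ± 8.41 units. DHRS2 (ENSG00000100867), KRT80 (ENSG00000167767), SLC7A11 (ENSG00000151012) and LURAP1L (ENSG00000153714) had log2 fold changes of -3.39, -3.07, -3.00 and -2.97. Ratios of group means give another order, since C10orf99, at 0.304 ± 0.526 and 34.5 ± 1.09 units, then lies above KRT1, and DHRS2, at 14.5 ± 0.545 and 0.729 ± 1.26 units, fell further than GDF15. MAP1B (ENSG00000131711), a microtubule-associated protein, stood at 10.6, 11.1 and 10.4 units in the parental libraries and was listed at 0 in all 3 sphere libraries. The list of matrix proteases and their inhibitors, to which MMP1 and MMP10 belong, had 13 of 28 members that rose and 9 that fell, and 14 and 10 when adjusted over the list alone, and was not called (camera adjusted p = 0.289). With limma and Benjamini-Hochberg adjustment, the adjusted p of these 16 genes lay between 1.97e-06 for OLFM4 and 0.00172 for DHRS2.

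**Figure D2:**
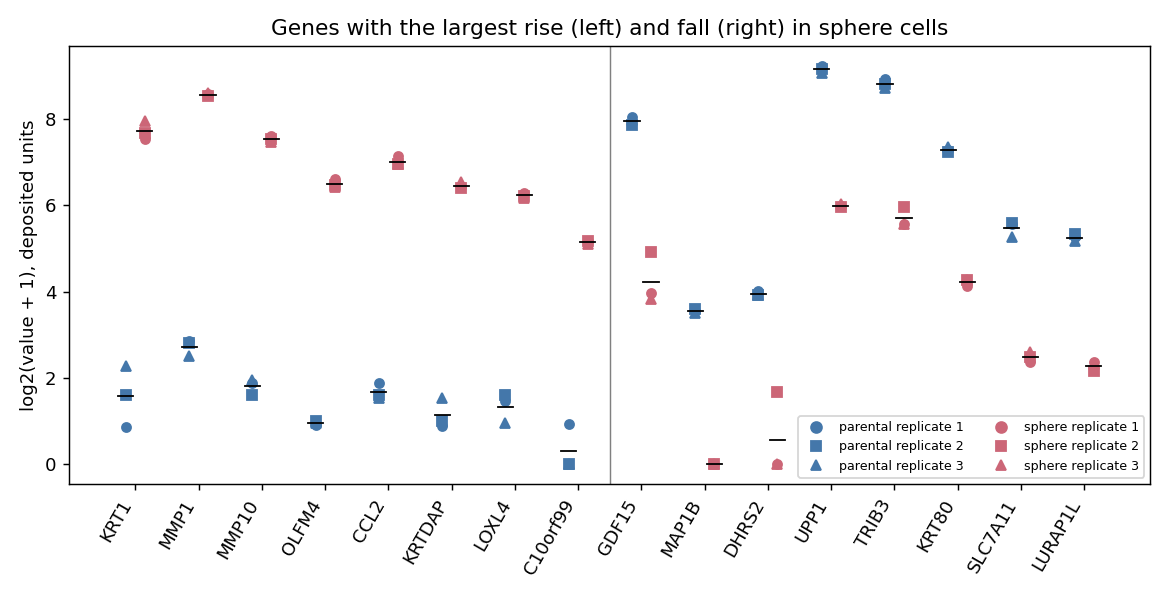
Values of the 8 genes with the largest rise and the 8 with the largest fall in sphere cells, each library a point on the log2(value + 1) scale of the deposited units and each short line the mean of 3 libraries. No overlap between the 2 groups was a condition for naming these 16 genes, and 65% of all tested genes met it.

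Across all tested genes, limma called 7315 at an adjusted p below 0.05, of which 3875 were higher and 3440 lower in sphere cells. At least 2-fold changes numbered 1570, with 1216 genes higher and 354 lower. Of these, 577 higher and 106 lower genes had means under 5 units, where the filter and rounding steps favour rises. A gene at 1 step in all sphere libraries and at 0 in the parental ones, such as TERT, passed the filter and counted as 2-fold. The reverse case failed the filter, because 1 step is below 1 unit in parental replicates 1 and 3. The split between higher and lower genes also depended on scaling. When the authors' scaling between libraries was undone, a choice made after the data were seen, 37.7% of called genes were higher against 53% as deposited, and the median log2 fold change of all genes moved by -0.15. Of the genes changed at least 2-fold, 77.5% were higher as deposited, 67.4% with the scaling undone and 63.3% after quantile normalization. Without the 3 libraries that held erythroid transcripts, 6059 genes were called and 1829 were changed at least 2-fold. Medians of gene lists below are given relative to the median of all tested genes.

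Of 46 gene lists fixed before the data were examined, 43 had at least 5 tested members and 15 were called with camera at its preset correlation, 11 toward higher and 4 toward lower values. None was called with an estimated correlation, where the smallest adjusted p was 0.095. That version of the test uses the few degrees of freedom left by 6 libraries, so a loss of calls was likely whatever the correlation. Fatty acid synthesis and hypoxia-response genes had estimated correlations of -0.0385 and -0.00833, below the preset 0.01, and still lost the call. Notch pathway and immediate early genes did too, at -0.0488 and -0.0115. The loss alone therefore does not decide whether correlation among members accounts for a call. Estimates were far above the preset for NF-kB and cytokine (0.534), histone (0.304), nuclear oxidative phosphorylation (0.256) and extracellular matrix genes (0.212). The other called lists lay between 0.086 and 0.159. If estimates above the preset hold, the preset p-values of those lists are too small.

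Genes of cholesterol and fatty acid synthesis rose together. Of 25 cholesterol synthesis and uptake genes, 24 rose and 0 fell, also when adjusted over the list alone, with a relative median log2 fold change of 2.07. HMGCS1, which makes the precursor of mevalonate, rose from 29.6 ± 0.588 to 238 ± 6.26 units, FDPS from 48.1 ± 2.21 to 295 ± 8.31 units and MSMO1 from 85.5 ± 4.18 to 558 ± 23.5 units. Camera gave an adjusted p of 2.53e-14 for this list, and adjusted p = 0.0948 with an estimated correlation. Of 12 fatty acid synthesis genes, 10 rose and 0 fell, also when adjusted over the list alone. The fatty acid synthase gene FASN rose from 32.8 ± 1.61 to 241 ± 6.91 units and the desaturase gene SCD from 205 ± 24.2 to 2444 ± 65.1 units. With camera the adjusted p was 1.88e-05, and adjusted p = 0.0948 with an estimated correlation. Of 16 genes of fatty acid oxidation and PPAR targets, 12 rose and 1 fell, also when adjusted over the list alone, led by the fatty acid binding protein gene FABP5 with a log2 fold change of 1.76. With the authors' scaling undone, and also without mitochondrially encoded genes, 7 rose and 1 fell. Tested with camera, the list had an adjusted p of 0.00696, and adjusted p = 0.348 with an estimated correlation.

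Targets of ATF4, the transcription factor of the amino acid stress response, fell together. Of 31 members, 29 fell and 1 rose, also when adjusted over the list alone, with a relative median log2 fold change of -1.20. The serine synthesis gene PSAT1 fell from 957 ± 28.7 to 207 ± 2.58 units, the mitochondrial folate enzyme gene MTHFD2 from 260 ± 9.49 to 61.3 ± 1.28 units, and SESN2 from 62 ± 1.42 to 9.18 ± 0.951 units. Camera gave an adjusted p of 2.53e-14, and adjusted p = 0.0948 with an estimated correlation. The list of chaperone and degradation genes of the endoplasmic reticulum also holds XBP1, which is neither. Of its 23 tested members, 13 fell and 2 rose, also when adjusted over the list alone. HSPA5, the main chaperone of that compartment, fell from 2150 ± 141 to 580 ± 26.6 units and XBP1 from 349 ± 14.4 to 109 ± 3.96 units. Camera gave this list an adjusted p of 4.92e-05, and adjusted p = 0.348 with an estimated correlation.

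Squamous differentiation genes were mostly higher in sphere cells. Of 49 tested members, 33 rose and 4 fell, and 34 rose and 4 fell when adjusted over the list alone. KRT4 rose from 2.82 ± 0.905 to 97.4 ± 3.65 units, CALML5 was listed at 0 in the parental libraries and stood at 7.41 ± 0.46 units in sphere cells, and KRT80 fell as described. The camera adjusted p was 3.72e-06, and adjusted p = 0.348 with an estimated correlation. Basal keratinocyte genes went both ways, with 13 of 22 higher and 7 lower, and 13 and 8 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.156). KRT15 rose from 169 ± 20 to 2542 ± 102 units and KRT14 from 1490 ± 93.1 to 10484 ± 431 units. Keratin genes have close paralogs and pseudogenes, and reads may be split among them. Of 9 simple-epithelium keratin and mucin genes, 5 rose and 2 fell, and 6 and 2 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.236). The mucin genes MUC4 and MUC20 had log2 fold changes of 2.34 and 1.29, and the keratin genes KRT8 and KRT18 fell by 1.36 and 1.70 on the log2 scale.

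**Figure D3:**
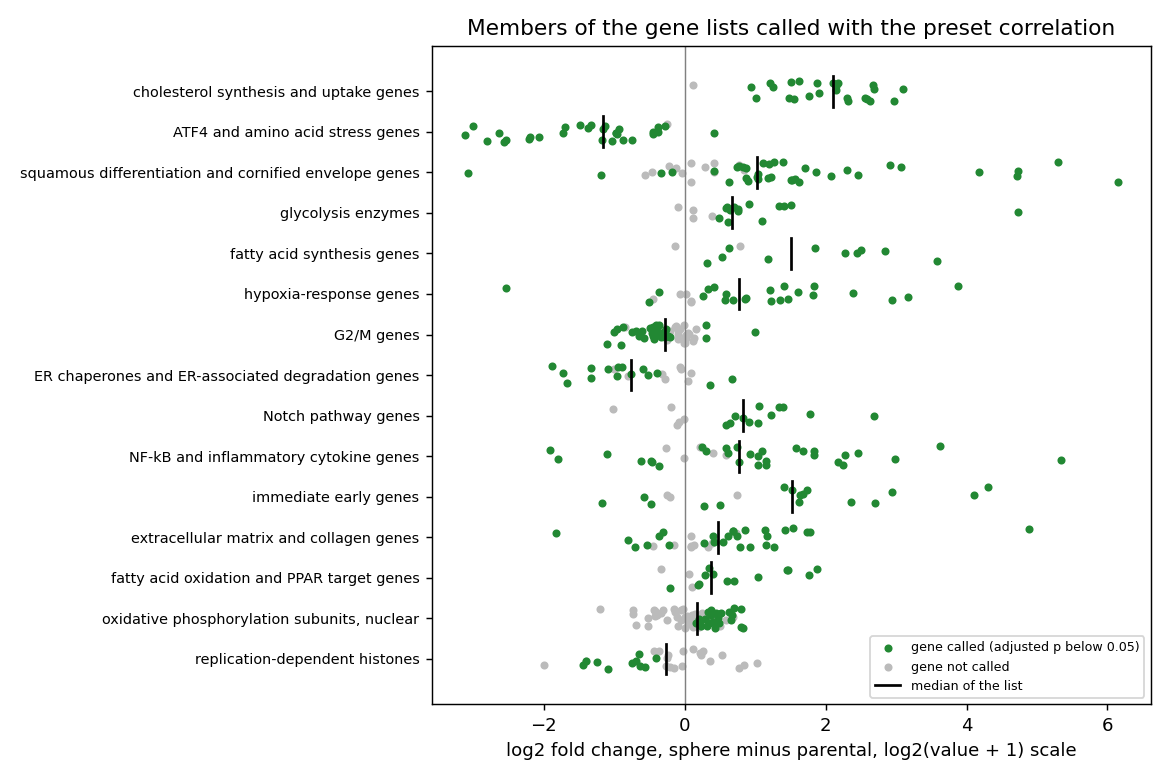
Log2 fold changes, sphere minus parental on the log2(value + 1) scale, of the members of the 15 gene lists called with camera at its preset correlation, with green points for called genes, grey for others and a black line at each median. Of the cholesterol synthesis genes 24 of 25 lie to the right as called genes, and of the ATF4 genes 29 of 31 lie to the left.

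Glycolysis and hypoxia-response genes were mostly higher. Of 18 glycolysis genes, 14 rose and 0 fell, also when adjusted over the list alone, with the aldolase gene ALDOC rising from 8.79 ± 0.895 to 259 ± 11.5 units and PGK1 from 200 ± 15 to 505 ± 15.9 units. With camera the adjusted p was 9.05e-06, and adjusted p = 0.285 with an estimated correlation. Of 28 hypoxia-response genes, 20 rose and 3 fell, also when adjusted over the list alone, and 19 and 5 without the 3 libraries with erythroid transcripts. NDRG1 rose from 64.1 ± 2.26 to 500 ± 34.3 units, and STC2, which is also in the ATF4 list, fell from 74 ± 1.48 to 12 ± 0.992 units. Tested with camera, the list had an adjusted p of 4.19e-05, and adjusted p = 0.0948 with an estimated correlation. Nuclear genes of oxidative phosphorylation rose in 25 of 69 cases with 0 falling, and in 23 when adjusted over the list alone, with a relative median of only 0.13. Camera gave this list an adjusted p of 0.0137, and adjusted p = 0.725 with an estimated correlation. That call ended without parental replicate 1 (adjusted p = 0.125), without sphere replicate 2 (0.0826), with the authors' scaling undone (0.0849), where 10 members rose and 1 fell, and without mitochondrially encoded genes (0.0741). It had a smaller p without parental replicate 3, with 30 rising (adjusted p = 0.00135, and adjusted p = 0.546 with an estimated correlation), and without the 3 libraries with erythroid transcripts, with 34 rising (6.88e-05, and adjusted p = 0.792 with an estimated correlation). Of 13 mitochondrially encoded genes, 4 rose, 1 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.103). Only 1 rose without parental replicate 3, without sphere replicate 2, without sphere replicate 3, with sphere replicates 1 and 3 averaged or with the authors' scaling undone, 2 rose without parental replicate 1 and 0 without the 3 libraries with erythroid transcripts. These genes took 15.4% to 16.7% of the parental totals and 18.6% to 20.3% of the sphere totals, and 0 of them were called after quantile normalization.

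The lists that bear on the stem cell label gave mixed results. Of 12 pluripotency and self-renewal factors, 7 rose and 2 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0881, and adjusted p = 0.348 with an estimated correlation). SOX2 rose from 2.83 ± 0.193 to 19.7 ± 0.976 units, ID1 from 276 ± 22.6 to 1099 ± 81.4 units, and KLF5, ID3, SOX9 and POU5F1 by log2 values of 0.80, 1.12, 0.41 and 0.78. The POU5F1 call ended in 4 of the 6 fits without 1 library, those without parental replicate 2 (limma adjusted p = 0.0787), parental replicate 3 (0.0708), sphere replicate 2 (0.0739) and sphere replicate 3 (0.0898). It also ended with quantile normalization (0.1), array weights (0.0546), sphere replicates 1 and 3 averaged (0.0564), the authors' scaling undone (0.117), without mitochondrially encoded genes (0.102) and without the 3 libraries with erythroid transcripts (0.267). The SOX9 call ended without these 3 libraries (limma adjusted p = 0.204), with the scaling undone (0.188) and without mitochondrially encoded genes (0.14). With the scaling undone 5 members of the list rose and 2 fell. KLF4 and BMI1 fell by 0.66 and 0.59 on the log2 scale. TERT was listed at 0 in the parental libraries and stood at 1.06 ± 0.0705 units in sphere cells, the level of a single rounding step. EZH2 was at 31.8 ± 1.43 and 31.7 ± 1.4 units and did not pass the test. MYC was at 46.9, 261 and 79.1 units in the parental libraries and 165.4, 166.9 and 168.4 units in the sphere libraries. It did not pass the test, and did so without parental replicate 2 (log2 fold change 1.44, limma adjusted p = 0.00501) and without the 3 libraries with erythroid transcripts (1.81, 0.00183). ID2 was at 3.16 ± 3.92 and 5.73 ± 4.58 units and did not pass the test, and did so without those 3 libraries (log2 fold change 1.20, limma adjusted p = 0.00429). POU5F1 has several pseudogenes that may share its reads.

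Of 14 surface and enzyme markers of tumour-initiating cells, 6 rose and 4 fell, and 6 and 5 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.667). The aldehyde dehydrogenase gene ALDH3A1 rose from 4.08 ± 0.339 to 84.1 ± 2.51 units, and PDPN, NGFR, LRIG1, CD47 and ALDH1A3 by log2 values of 1.15, 0.87, 0.66, 0.64 and 0.36. ITGB1, EPCAM, MET and CD44 fell by 0.49, 0.67, 0.57 and 0.19 on the log2 scale. CD24 was at 39 ± 9.07 and 36.7 ± 1.18 units and ITGA6 at 288 ± 10.6 and 264 ± 2.76 units, and neither passed the test. ITGA6 passed it without parental replicate 3 (limma adjusted p = 0.0273), with array weights (0.023) and with a pseudocount of 0.1 (0.0491). ALDH1A1 was at 0.32 ± 0.553 and 1.06 ± 0.0705 units, the sphere level being that of a single rounding step, and did not pass the test. It passed without parental replicate 3 (log2 fold change 1.04, limma adjusted p = 0.00152), with array weights (0.0167) and without the 3 libraries with erythroid transcripts (0.00242). The ALDH1A3 call ended without parental replicate 1 (limma adjusted p = 0.0572), without sphere replicate 1 (0.06), with the authors' scaling undone (0.235) and without mitochondrially encoded genes (0.161). The CD44 call ended with quantile normalization (limma adjusted p = 0.0572), without sphere replicate 1 (0.0581), without mitochondrially encoded genes (0.0709) and without the 3 libraries with erythroid transcripts (0.141).

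Notch pathway, immediate early and inflammatory genes were also mostly higher. Of 17 Notch pathway genes, 12 rose and 0 fell, also when adjusted over the list alone. Without the 3 libraries with erythroid transcripts 13 rose and 2 fell. The feedback gene NRARP rose from 40.5 ± 2.81 to 266 ± 8.53 units and NOTCH3 from 32.4 ± 1.1 to 83.5 ± 3.48 units. The camera adjusted p was 0.000459, and adjusted p = 0.118 with an estimated correlation. Of 19 immediate early genes, 13 rose and 3 fell, also when adjusted over the list alone, with EGR1 going from 20.5 ± 1.18 to 425 ± 4.37 units and FOS from 5.03 ± 0.305 to 103 ± 2.98 units. With camera the adjusted p was 0.00256, and adjusted p = 0.149 with an estimated correlation. Of 35 NF-kB and cytokine genes, 23 rose and 7 fell, and 25 and 7 when adjusted over the list alone. In parental replicate 3, 31 of the 35 members were lower than in both other parental libraries, with a median log2 difference of -0.32 from their mean. CXCL1 rose from 27.9 ± 5.36 to 352 ± 22.1 units and CXCL8 from 66.4 ± 10.1 to 322 ± 4.87 units. Tested with camera, the list had an adjusted p of 0.00158, and adjusted p = 0.725 with an estimated correlation.

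Of 36 extracellular matrix genes, 20 rose and 7 fell, and 24 and 9 when adjusted over the list alone. FBLN1 rose from 17.9 ± 0.221 to 61.9 ± 1.94 units and SPARC from 109 ± 2.96 to 375 ± 12.8 units, while the tenascin gene TNC fell from 225 ± 13 to 62.7 ± 4.39 units. FBLN1 is also among the 4 tested fibroblast markers, of which 2 rose, FBLN1 and LUM, and 1 fell. The matrix genes that fell numbered 4 without parental replicate 1, parental replicate 2, sphere replicate 1 or sphere replicate 2. Camera gave this list an adjusted p of 0.00332, and adjusted p = 0.617 with an estimated correlation. Of 13 mesenchymal genes, 3 rose and 5 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.578). SNAI2 rose from 33.7 ± 1.35 to 89.4 ± 0.71 units and AXL fell from 76.4 ± 7.97 to 12.7 ± 0.679 units. VIM, chosen after its values were seen, stood at 0.1, 19.2 and 164.9 units in the parental libraries and 0, 18.5 and 0 units in the sphere libraries, and its high values lay in the 3 libraries with erythroid transcripts.

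More genes of the G2 and M phases fell than rose. Of 54 members, 27 fell, 3 rose and 24 were not called, and 28 fell and 3 rose when adjusted over the list alone. The mitotic kinase genes AURKA and NEK2 fell from 224 ± 13.7 to 111 ± 2.1 units and from 88.4 ± 5.6 to 40.5 ± 1.95 units. The camera adjusted p was 4.82e-05, and adjusted p = 0.348 with an estimated correlation. Of 54 S-phase genes, 18 rose and 5 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.382). With the authors' scaling undone 9 S-phase genes rose and 5 fell, and without mitochondrially encoded genes 9 rose and 2 fell. The S-phase genes that fell numbered 3 without parental replicate 3, 2 without sphere replicate 1 or sphere replicate 2, 2 with sphere replicates 1 and 3 averaged and 1 without the 3 libraries with erythroid transcripts. The difference between the G2/M and S-phase lists was not tested. Of 30 replication-dependent histone genes, 10 fell and 0 rose, and 9 fell when adjusted over the list alone, with a camera adjusted p of 0.044, and adjusted p = 0.725 with an estimated correlation. The histone call ended without sphere replicate 1 (adjusted p = 0.155), without sphere replicate 3 (0.0685), without parental replicate 3 (0.0648), with a minimum mean of 5 units (0.114), without a filter (0.0525), with the authors' scaling undone (0.12), without mitochondrially encoded genes (0.0728) and with sphere replicates 1 and 3 averaged (0.0964). It had a smaller p without sphere replicate 2 (adjusted p = 0.00185), without parental replicate 1 (0.0176) and without the 3 libraries with erythroid transcripts (0.00514, and adjusted p = 0.655 with an estimated correlation). HIST1H1C, chosen after its values were seen, was at 360, 525.1 and 1073.5 units in the 3 libraries with erythroid transcripts, parental replicates 2 and 3 and sphere replicate 2, against 218.1 units in parental replicate 1 and 260.7 and 254.2 units in sphere replicates 1 and 3. HIST1H4C, chosen in the same way, was at 0, 35.6 and 201.4 units in those 3 libraries and at 0.6, 1.3 and 0.1 units in the others. Without the 3 libraries 11 histone genes fell and 2 rose.

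Some markers of other cell types were expressed and some differed between the groups. Of 14 fibroblast, 17 leukocyte and 12 endothelial markers, 4, 4 and 2 passed the filter, too few for a list test, and of 14 neural markers 5 did (camera adjusted p = 0.504). Of these, 2 fibroblast markers rose and 1 fell (3 and 1 when adjusted over the list alone), 1 leukocyte marker rose, 1 neural marker rose and 1 fell, each also when adjusted over the list alone, and 0 endothelial markers were called. Without parental replicate 1 the fibroblast marker COL1A2 and the leukocyte marker ITGAM also passed the test (log2 fold change 1.04 and limma adjusted p = 0.00148 for each), both at 1.06 ± 0.0705 units in sphere cells, the level of a single rounding step. After quantile normalization the endothelial marker CDH5 (log2 fold change -0.58, limma adjusted p = 0.0437) and the neural marker MAP2 (-1.24, 0.00279) passed it as lower, MAP2 also without sphere replicate 1 (0.0187), with a pseudocount of 5 (0.0356) and with sphere replicates 1 and 3 averaged (0.0327). The fibroblast markers LUM and FBLN1 rose from 0.941 ± 0.0678 to 21.8 ± 2.98 units and from 17.9 ± 0.221 to 61.9 ± 1.94 units, and the leukocyte marker CD14 rose from 14.2 ± 0.957 to 28.9 ± 0.639 units. The fall was in COL1A1, and its call ended in 4 of the 6 fits without 1 library, those without parental replicate 1 (limma adjusted p = 0.0804), parental replicate 2 (0.0757), sphere replicate 1 (0.0824) and sphere replicate 2 (0.0719), and also without the 3 libraries with erythroid transcripts (0.0819) and with sphere replicates 1 and 3 averaged (0.0511). The neural marker NEFL rose from 3.45 ± 0.386 to 5.27 ± 0.733 units, a call that ended with the authors' scaling undone (limma adjusted p = 0.136), without mitochondrially encoded genes (0.109) and without the 3 libraries with erythroid transcripts (0.0535). The neural marker TUBB3 fell from 72.7 ± 14.3 to 15.2 ± 0.924 units. CD68 was at 64.1 ± 6.88 and 63.5 ± 3.92 units and did not pass the test. LAPTM5 was at 39.4 and 16.4 units in parental replicate 3 and sphere replicate 2 and at about 2 units or less in the other libraries. Leaving out the 3 libraries with erythroid transcripts called 20 lists, among them interferon-response genes (21 of 40 fell, camera adjusted p = 0.000282), cytosolic ribosomal proteins (0.00129), S-phase genes (0.0124), EGFR ligands and ERK feedback genes (0.026) and pluripotency factors (0.0338), none of which was called with all 6 libraries. With all 6, 7 interferon-response genes fell, and without parental replicate 3 alone 25 did (camera adjusted p = 5.11e-05, and adjusted p = 0.224 with an estimated correlation). Without the 3 libraries 0 lists were called with an estimated correlation, where the smallest adjusted p was 0.655. With 1 parental library left, that fit assumes that it varies like the 2 sphere libraries.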

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

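The alternatives that undid the authors' scaling, averaged sphere replicates 1 and 3, left out mitochondrially encoded genes or left out the 3 libraries with erythroid transcripts were chosen after seeing the data. The number of changed genes, 7315, stayed within 1.5 times under every alternative run, from 5492 without mitochondrially encoded genes to 7667 with array weights, and from 6149 to 7310 with 1 library left out. The 1570 genes changed at least 2-fold became 623 with a pseudocount of 5, which shrinks low genes, and 889 with a minimum mean of 5 units, which tests fewer genes, and ranged from 1516 to 1671 with 1 library left out. The 15 called lists became 0 with an estimated correlation, also without parental replicate 3, and 14 to 16 with 1 library left out at the preset correlation. With an estimated correlation the test has few degrees of freedom here, so that loss alone does not decide whether correlation accounts for the calls. Estimates for the called lists ran from -0.0488 to 0.534. If they hold, the preset was too low for some of these lists. The replicate block called 6176 genes, 1535 at least 2-fold and 15 lists, and with it POU5F1 (limma adjusted p = 0.0857), COL1A1 (0.0829), MT-ND4 (0.0728), MT-ND4L (0.0719) and MT-ND5 (0.0581) were not called. Deviations of libraries that share a replicate number had correlations of 0.33, 0.12 and -0.27. Libraries with different numbers were not compared in this way, so these values do not decide whether the numbers pair the libraries.

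Over 196 named genes, 3579 of 3699 comparisons with an alternative kept direction and side of the threshold, 76 lost the call, 18 gained it and 26 changed sign. The log2 fold changes of MT-ND4, MT-ND4L and MT-ND5 were called as deposited and turned to -0.20, -0.18 and -0.01 under quantile normalization. The other sign changes were in genes not called as deposited, with values near 0 or a wide spread. LAPTM5 was at -0.14 with a pseudocount of 5 and from -0.71 to 1.94 with 1 library left out. CD68 was at 0.01 with median-ratio scaling, 0.01 with quantile normalization, 0.02 with sphere replicates 1 and 3 averaged, and from -0.09 to 0.06 with 1 library left out. EZH2 was at 0.02 with median-ratio scaling, 0 with array weights, 0.01 without the 3 libraries, and from -0.04 to 0.03 with 1 library left out. CD24 was at 0 with array weights, 0.04 without the 3 libraries and from -0.18 to 0.11 with 1 library left out. SYP was at 0 with array weights, 0.12 without the 3 libraries and from -0.23 to 0.09 with 1 library left out. The cause was not tested. Read depth is unknown and rounding limits genes of a few units.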

Other observations

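Several lists that were not called held large changes in single genes. Of 23 Wnt pathway genes, 7 rose and 9 fell (camera adjusted p = 0.816). The Wnt inhibitor gene DKK1 fell from 355 ± 8.82 to 78.2 ± 1.47 units, while the ligand genes WNT4 and WNT10A rose from 2.83 ± 0.193 to 17.3 ± 0.805 units and from 26.7 ± 1.52 to 84.1 ± 5.02 units. Of 23 EGFR ligands and ERK feedback genes, 6 rose and 12 fell (camera adjusted p = 0.0784), with the ligand gene AREG falling from 204 ± 19.7 to 26.8 ± 2.39 units and the receptor gene EGFR rising from 228 ± 3.6 to 507 ± 20.8 units. Of 21 antigen presentation genes, 10 rose and 6 fell (camera adjusted p = 0.578), and the class II genes HLA-DRA and CD74 rose from 47.1 ± 10.4 to 199 ± 7.26 units and from 91.1 ± 14.1 to 286 ± 9.32 units. Of 23 YAP/TAZ target genes, 8 rose and 10 fell (camera adjusted p = 0.62), and 4 rose and 11 fell with the authors' scaling undone, with CCN2 rising from 7.85 ± 0.736 to 96.8 ± 2.97 units. For the Wnt and YAP/TAZ lists the median log2 fold changes relative to all tested genes were 0.09 and 0.06 while the camera direction was toward lower values.

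Of the tests below, those on erythroid transcripts, on rounding and on parental replicate 3 were chosen only after the result was seen.

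Transcripts typical of red-cell precursors were present in 3 libraries from both groups, parental replicates 2 and 3 and sphere replicate 2. In these, HBG2 was at 1000, 349.5 and 159.8 units and HBA1 at 422.4, 321.7 and 290.6 units. A difference between sphere and parental cells is argued against, since libraries of both groups lacked the transcripts, with at most 0.9 units of summed globins. One source of fixed composition in all 3 libraries is argued against as well. GATA1, KLF1 and NFE2 summed to 83.7 units in parental replicate 3 and to 0.0458 units in parental replicate 2, which held more globin transcripts. The computed ratio of these 3 genes to globins was 2810 times lower in parental replicate 2. That figure rests on values below 1 rounding step, so only a much lower ratio can be read from it, not its size. For parental replicate 3 and sphere replicate 2 that ratio differed 1.35 times, but over the 31 genes below 1 unit in the other libraries and at 5 units or more in both of these, the ratio between the libraries had a 90th percentile 17.2 times its 10th, which argues against a fixed composition here too. Erythroid RNA or reads remain a candidate explanation that the tables do not decide: of 38 markers listed, 12 stayed below 1 unit in the other libraries and at least 5 of these reached 5 units in each of the 3, but every one of the 12 had been looked at before the list was written, and 12 others are expressed in the other SCC4 libraries too.

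More genes were at least 2-fold higher than lower in sphere cells, 3.44 times as many. Rounding of low values as the whole cause is argued against, since the ratio was 2.41 among genes of at least 20 units. The filter and the rounding steps do add to the excess at low values, where the ratio was 5.44 among genes under 5 units. There a gene at 1 step in the sphere libraries only counts as 2-fold higher, while a gene at 1 step in the parental libraries only fails the filter. How many genes this concerns was not counted. Scaling between libraries as the whole cause is argued against by a lowest ratio of 1.72 over 3 other scalings, although that ratio suggests that scaling may set part of the excess. Erythroid reads are argued against by a ratio of 3.86 without those libraries. A difference between the culture forms stays open as a hypothesis.

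Interferon-response genes were lower in parental replicate 3 than in parental replicates 1 and 2, in 39 of 40 members, with a median log2 difference of -0.58. Dilution by erythroid reads is argued against, because the list lay -0.59 from the median of all genes of at least 20 units. Whether the erythroid transcripts of parental replicate 3 go with this in another way stays open. The median of -0.02 between parental replicates 2 and 1 does not decide it. That value comes from a library whose erythroid transcripts differed in composition. No biological explanation was tested, since no label separates these replicates.

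The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 7315 genes and the highest other split 10, and for changes of at least 2-fold the values were 1570 and 10. For gene lists the real split called 15 and the highest other split 14, so the number of lists called at the preset correlation does not set the real grouping apart from other splits.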
